A study of Homo sapiens with 12 samples.

How the data were processed

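RNA was measured in 12 libraries of SKOV-3, an established human ovarian adenocarcinoma cell line, in 4 groups of 3: parental cells, parental cells with a double knockout of the histone demethylase genes KDM5A and KDM5B, cisplatin-resistant cells, and cisplatin-resistant cells with the same double knockout. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a group came from separate cultures, so p-values then measure only the spread between these libraries, which may be technical.

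The values are raw read counts per gene as deposited by the authors. Per the labels' protocols the libraries were made from poly(A) RNA with a kit that keeps strand. Per the submitters' processing notes, Trim Galore 0.6.10, STAR 2.7.10a and featureCounts 2.0.1 were used with the human build GRCh38; the annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies, such as ribosomal protein genes, ferritin heavy chain, aldo-keto reductases, PSG5 and the pseudogene ANKRD20A9P, may therefore share reads. The deposited table held 59542 gene rows with 59498 identifiers; 44 identifiers stood on 2 rows, and those rows held 0 reads. A second deposited copy of the table was equal in all 833588 cells compared and was not used. In 2 columns the name of the resistant line was misspelled by a letter, and these were matched by the rest of the name to the resistant libraries without the knockout numbered 2 and 3. Names, biotypes and coordinates came from GENCODE release 29 on GRCh38, which holds 57380 of the identifiers and 99.95% of the counts.

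Total counts ran from 15659352 to 19706754 per library. Pairs of libraries within a group differed far beyond sampling noise (chi-square per degree of freedom 27.1 to 219.5), so no library was counted as a duplicate.

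The following was computed from the deposited counts. Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which kept 17947, and scaled with TMM factors. All 12 libraries entered a single fit with a mean per group, and contrasts were tested with edgeR's quasi-likelihood test (robust) with Benjamini-Hochberg adjustment at 0.05. A total of 5 contrasts were tested: resistant against parental, knockout in parental cells, knockout in resistant cells, resistant against parental among knockout libraries, and the difference of the knockout effects. Adjusted p-values below come from this test unless another is named. Levels are in CPM, counts scaled to the effective library size, given as mean ± SD over 3 libraries. The SE of a log2 fold change is its absolute value divided by the square root of the test's F statistic. Where a group had 0 reads for a gene, a fold change is given as a lower bound against 3 counts over the group's 3 libraries; with 1 to 3 counts it is a ratio with a 95% exact counting interval. Bounds and intervals cover counting error only, and reads carry no molecular identifiers.

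A total of 25 gene lists with 759 entries, all found in the table, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 25 lists of a contrast, and again with an estimated correlation and with fry. Markers of 6 other cell types were read as levels. Named genes follow a rule: per contrast the 8 largest increases and 8 largest decreases (4 and 4 for the last 2 contrasts) among protein-coding genes that passed, had at least 5 CPM in the higher group and whose libraries did not overlap; the 6 largest per direction of the genes changed in opposite ways; up to 4 members of each list that passed with at least 1 CPM; and KDM5A, KDM5B and KDM5C. Some genes that the rule names are not reported here. For the difference of the knockout effects overlap was not considered. Groups, tests, lists, the rule and the first set of alternatives were fixed before the data were examined.

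Alternatives were median-of-ratios factors, library size alone, no filter beyond 1 count, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the libraries compared alone, the replicate number as a block, leaving out each library, and an absolute log2 fold change of at least 1. Added after the data were seen were 3 further forms of the block, leaving out both parental libraries numbered 3, and 100000 draws for the test of chromosome windows. The planned 10000 draws over windows of 10 Mb with at least 20 genes cannot call a lone window: in simulated counts with 1 shifted window of 263, the smallest adjusted p was 0.0526, and the window was called with 100000 draws. With 4 shifted windows all 4 were called at either number.

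Whether replicate numbers pair the libraries was checked by correlating deviations from group means across genes. Parental and parental knockout libraries with the same number correlated at 0.66, 0.77 and 0.78, so the numbers were taken to pair them; the pairing comes from the titles' numbers. Such a block can be set up in 4 ways, with very different counts of calls, and all are printed. The planned one fits 1 effect per number across all 12 libraries. The others fit the numbers within each background, on the parental libraries within the fit of all 12, or on the 6 parental libraries alone.

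The tests were tried on simulated counts with a seeded set of changed genes. Counts were drawn with each gene's mean over all 12 libraries and the real depths and spread. Changed genes were taken only from those with a mean of at least 1 CPM. For resistant against parental, with 17472 genes tested, 6.0% of genes changed 2-fold, 55.2% changed 4-fold and 84.8% changed 8-fold were recovered. For the knockout in parental cells (17479 genes) the shares were 1.5%, 56.7% and 80.3%, and for the knockout in resistant cells (17420 genes) 6.0%, 59.7% and 86.4%. False calls made up 5.8%, 2.1% and 3.8% of the calls.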

Results

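Poly(A) RNA was sequenced from SKOV-3, a human ovarian adenocarcinoma cell line, and from its cisplatin-resistant derivative, each without and with a double knockout of KDM5A and KDM5B, which encode demethylases of lysine 4 on histone H3. Each of the 4 groups held 3 libraries, and totals ran from 15659352 to 19706754 counts per library. The series title places KDM5 proteins in cisplatin resistance, so the comparisons ask how resistant cells differ from parental cells and which transcripts the knockout moves in each.

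The transcript of KDM5A (ENSG00000073614, GRCh38 chromosome 12, 280129 to 389454) was lower in the knockout libraries of both backgrounds. It fell from 37.3 ± 5.6 CPM (SD, n = 3) to 19.7 ± 3.6 in parental cells and from 37.4 ± 3.5 to 14.8 ± 2.8 in resistant cells, and each of the 6 knockout libraries lay below every control of its background. A two-sided exact permutation test within backgrounds gave p = 0.005, the smallest it can give. KDM5B (ENSG00000117139, chromosome 1, 202724495 to 202809470) measured 57.9 ± 19.3 CPM in parental cells and 53.8 ± 26.9 in their knockout, and 76.6 ± 36.1 and 56.7 ± 28.2 in resistant cells, with 2 of 6 knockout libraries below every control (exact permutation p = 0.445). KDM5C (ENSG00000126012, chromosome X, 53191321 to 53225422), a paralog that was not targeted, gave p = 0.465 in the exact permutation test. Over all genes tested, edgeR's adjusted p for KDM5A was 1 in parental cells (log2 fold change -0.92 ± 0.25 SE) and 0.0524 in resistant cells (-1.34 ± 0.25). With the replicate number as a block within each background, chosen after the data were seen, the parental value was -0.93 with an adjusted p of 0.0468. An allele with a frameshift can keep its transcript, so these levels do not measure the proteins.

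**Figure D1:**
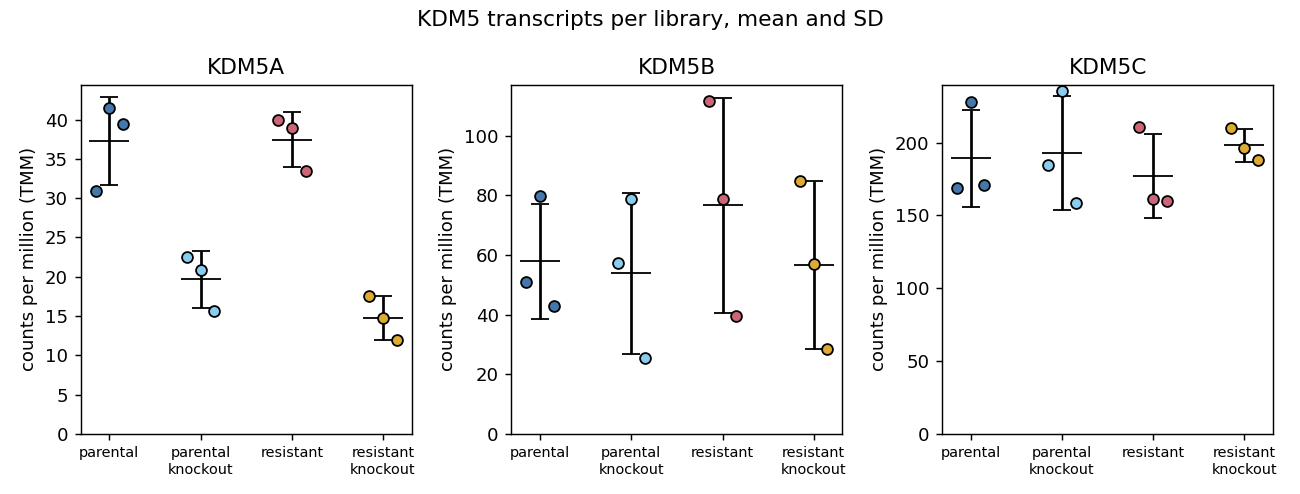
CPM of KDM5A, KDM5B and KDM5C in each of the 12 libraries by group (points), with the mean and SD of each group of 3. KDM5A lies below every control of its background in 6 of 6 knockout libraries, KDM5B in 2 of 6.

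Resistant cells differed from parental cells in 5030 of 17947 genes (28.0%), of which 2728 were higher and 2302 lower, and 4377 changed at least 2-fold. Genes with no reads in the parental libraries and clear levels in resistant cells included LDOC1 (ENSG00000182195, chromosome X, 141175745 to 141177125; 92.3 ± 6.9 CPM, at least 1585-fold higher), CYB5A (at least 650-fold) and BMP7, a bone morphogenetic protein (at least 533-fold). TENM2 (ENSG00000145934, chromosome 5, 167284799 to 168264157) rose from 0.02 ± 0.03 to 614 ± 253 CPM, a ratio of 31600 with a counting interval of 5670 to 1250000. ALDH1A1, an aldehyde dehydrogenase, rose from 0.04 ± 0.03 to 113 ± 60.1 CPM, a ratio of 2900 (802 to 23900). In the other direction SH2D4A fell from 40.9 ± 9.0 CPM to no reads (at least 711-fold lower) and the basal keratin KRT5 from 37.6 ± 44.5 (at least 706-fold).

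Further genes with large increases were SLC19A3, a thiamine transporter (at least 373-fold higher), TMEM218 (at least 351-fold) and MAGEH1 (at least 282-fold). Further large decreases were in FOXQ1 (at least 422-fold lower), IGFBP1 (at least 406-fold), MARVELD1 (at least 378-fold), PDPN (at least 363-fold) and the cytokine gene IL6, with a ratio of parental to resistant of 3230 (894 to 26700). For the genes named so far in this contrast edgeR's adjusted p ran from 1.02e-06 for TENM2 to 0.00898 for KRT5.

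Among the mesenchymal and extracellular matrix genes, 22 of 37 tested were higher and 4 lower in resistant cells. SPARC, a matrix glycoprotein, rose from 0.92 ± 1.32 to 1459 ± 773 CPM and the collagen COL1A1 from 0.93 ± 1.18 to 671 ± 301, while POSTN (ratio 465, 83.0 to 18400) and COL6A3 (ratio 444, 79.3 to 17600) started near 0. Fibroblast markers hold COL1A1 and COL6A3 too, and 5 of 9 reached 1 CPM in resistant cells against 1 of 9 in parental cells. Of 26 NF-kB and cytokine genes 15 were lower and 1 higher, among them IL6, IL1A (132 ± 100 to 0.12 ± 0.11 CPM), CXCL8 (357 ± 385 to 1.17 ± 0.20) and TNF (10.2 ± 4.8 to 0.10 ± 0.07). Ovarian carcinoma lineage genes were 4 higher and 8 lower of 19, with falls in LCN2, SLPI, FOLR1 (log2 fold change -6.04 ± 0.85 SE) and MSLN (-5.86 ± 0.61). Cytosolic ribosomal protein genes were 0 higher and 7 lower of 56, with RPLP0 at -1.54 ± 0.36 and RPL13A at -1.46 ± 0.38; adjusted over the list alone, 4 were lower. These genes made up 5.79%, 5.40% and 3.72% of counts in parental libraries 1, 2 and 3 and 2.20%, 4.43% and 3.58% in resistant libraries 1, 2 and 3, so resistant library 1 stood apart. These 4 lists were called by camera at the preset correlation (adjusted p 7.16e-05, 4.75e-05, 0.0366 and 0.00012) and 0 lists with an estimated correlation (lowest adjusted p = 0.50). Other splits of the same libraries called up to 13 lists, so a preset call alone does not set a list apart.

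Genes tied to platinum handling moved both ways. Of 19 cisplatin transporter genes 6 were higher and 3 lower: the organic cation transporters SLC22A2 (ratio 81.9, 27.7 to 400) and SLC47A1 (0.81 ± 0.65 to 21.6 ± 7.4 CPM) and the copper exporter ATP7A (7.87 ± 1.94 to 32.4 ± 24.3) rose, and SLC22A3 fell. The metal-binding metallothioneins MT2A (138 ± 36.0 to 930 ± 546 CPM) and MT1X (21.2 ± 11.6 to 76.9 ± 35.0) rose and MTF1 fell, of 3 tested. In the NRF2 and glutathione list 7 of 32 were higher and 8 lower, with GSTA4 up and AKR1C1, AKR1C2 and the ferritin chain FTH1 (7925 ± 3036 to 181 ± 28.0 CPM) down. Nucleotide excision repair genes had 2 higher and 4 lower of 30 (GTF2H3 at -2.04 ± 0.38), and 0 and 2 adjusted over the list alone; homologous recombination and Fanconi genes had 0 and 2 of 37 (RBBP8 at -3.03 ± 0.54 and BRCA2 at -1.70 ± 0.39), and mismatch repair and translesion synthesis 1 and 2 of 15 (MLH3 at -1.06 ± 0.22).

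The unfolded protein and integrated stress response list split, with 6 of 28 higher and 12 lower: TRIB3 (-4.01 ± 0.93), ATF3 and PPP1R15A fell, and CRELD2, an endoplasmic reticulum protein gene, rose (3.34 ± 0.38). Epithelial genes were 5 higher and 10 lower of 27, with CLDN3, KRT19 (152 ± 98.8 to 1.58 ± 1.38 CPM) and CLDN7 down. Interferon-stimulated genes were 9 higher and 3 lower of 39, with IFI6 (4.19 ± 0.90), MX1 and TRIM22 up and BST2 (-4.61 ± 0.67) down, and MHC class I genes 5 higher and 1 lower of 20 (PDIA3 and CALR up, PSMB8 down). Counts of higher and lower genes were 3 and 7 of 29 for p53 targets (TP53I3 up, SESN2 down), 3 and 7 of 30 for apoptosis regulators (BCL2A1 up, BIRC3 down), 4 and 4 of 19 for stem-like and aldehyde dehydrogenase genes (ALDH1A3 up, ALDH3A1 down) and 6 and 4 of 32 for hypoxia and glycolysis genes (EGLN3 up, VEGFA down). They were 4 and 4 of 25 for immediate early and heat shock genes (EGR1 up, FOSL1 down), 5 and 2 of 25 for cholesterol genes (ACAT2 up, EBP down) and 7 and 0 of 46 for oxidative phosphorylation (COX4I1 up), where 0 passed adjusted over the list alone. Germline genes had 3 and 0 of 8 (MEIOB up), H3K4 enzymes 2 and 3 of 22 (KDM1B up, SETD7 down), mitosis genes 0 and 1 of 36 (CDC25B down) and replication genes 0 and 1 of 42 (POLA1 down). Adjusted over the list alone, replication genes had 0 and 0 and H3K4 enzymes 1 and 3. Camera called 4 of the 25 lists in this contrast, those given first. Without parental library 2 the count of changed genes was 3081.

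**Figure D2:**
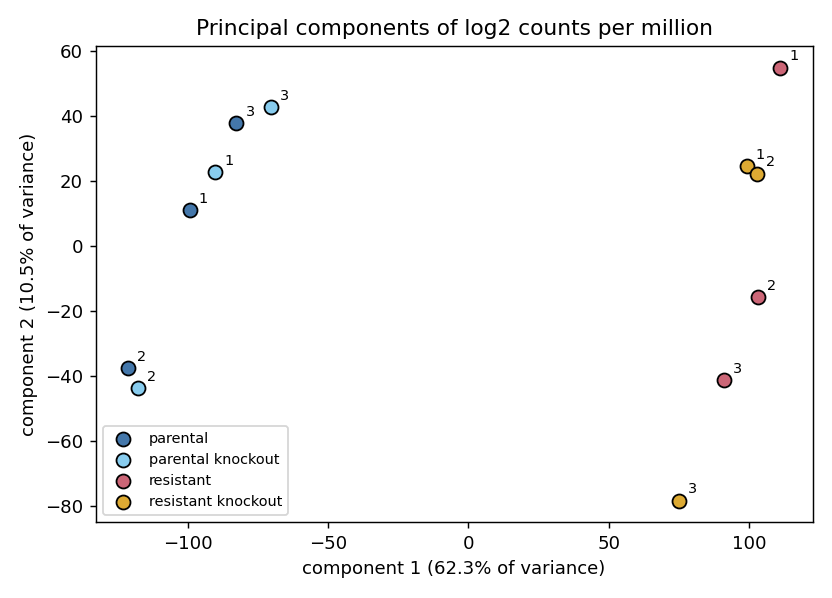
First and second principal components of log2 CPM for the 12 libraries, with the share of variance on each axis and the replicate number beside each point. Component 1 (62.3% of variance) separates parental from resistant libraries, and parental libraries with the same number lie close together.

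Among the knockout libraries, resistant cells differed from parental cells in 4281 genes, 2445 higher and 1836 lower. LDOC1 (at least 1389-fold), CYB5A (at least 1058-fold), the fibrinogen chain gene FGB (at least 911-fold) and EPB41L3 (at least 820-fold) were highest against knockout parental cells with no reads. PTX3 (55.1 ± 80.1 to 0.11 ± 0.05 CPM), IL6 (253 ± 278 to 0.81 ± 0.34), THNSL2 and CXCL8 (916 ± 1165 to 3.85 ± 0.83) were lowest. Matrix genes were 20 higher and 3 lower of 37, with SPARC reaching 1535 ± 254 CPM and COL1A1 3651 ± 1008, and NF-kB and cytokine genes 1 higher and 16 lower of 26. These 2 lists were called at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.33), and other splits called up to 11. The count was 4 without parental knockout library 1 or 3 or resistant knockout library 3, and 5 with a filter of 1 count only. Across genes the fold changes correlated with those without the knockout at r = 0.89 (rho 0.85); genes are not independent replicates. The contrasts called 3315 genes in the same direction, with 371.6 higher and 235.5 lower expected of independent lists, and 1 in opposite directions. Scaled by library size alone the split was 2928 higher and 1368 lower, with the median of all genes shifted by 0.15 on the log2 scale. Without resistant knockout library 1 or 2 the counts were 2715 and 2714.

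In parental cells the knockout changed 0 of 17947 genes by edgeR, with 539 at an unadjusted p under 0.05; DESeq2 called 11, limma-voom 1 and edgeR with a filter of 1 count only 83. With the replicate number as a block the count was 1 in the planned form. In the 3 forms chosen after the data were seen it was 0 on the parental numbers with all 12 libraries, 154 (77 higher, 77 lower) within backgrounds and 1206 (553 higher, 653 lower of 15903 tested) on the parental libraries alone. The last 2 shared 139 genes with the same sign. Among these, the chemokine gene CCL2 measured 0.22 CPM in parental and 6.03 CPM in knockout cells (log2 fold change 4.77 ± 0.36 SE, adjusted p 7.17e-05 by edgeR on the parental libraries alone), and the acute-phase gene SAA1 18.9 and 83.7 CPM (2.09 ± 0.15). KRT5 measured 37.6 and 6.37 CPM (-2.61 ± 0.21) and the lipid flippase gene ATP10A 2.33 and 0.10 CPM (-4.46 ± 0.50). These 4 genes were chosen after their values were seen.

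Of 25 lists, 5 were called in parental knockout cells at the preset correlation. NF-kB and cytokine genes (median log2 fold change 0.58) and oxidative phosphorylation genes (0.17) were on the higher side, and interferon-stimulated genes (-0.43), mitosis genes (-0.16) and unfolded protein and stress response genes (-0.17) on the lower side, with 0 single members past the test. With an estimated correlation 0 were called (lowest adjusted p = 0.87), and other splits called up to 10. The count was 2 without parental knockout library 2, 3 without parental library 3 or parental knockout library 1, and 8 without parental knockout library 3 or with a filter of 1 count only. The mitochondrial share of counts also differed between these libraries: 7.75%, 5.34% and 7.55% in parental libraries 1, 2 and 3 against 10.7%, 6.54% and 16.3% in the parental knockout libraries.

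In resistant cells 38 genes were higher after the knockout and 0 lower by edgeR, with 1426 at an unadjusted p under 0.05. With the planned replicate block 53 were higher and 2 lower. With a block within backgrounds, a form chosen after the data were seen, 608 were higher and 331 lower, though pairing by number is unclear in resistant cells. DESeq2 called 214 higher and 35 lower, and edgeR with a filter of 1 count only called 451, of which 416 are genes the stricter filter keeps. KRT81, a hair keratin, rose from 3.04 ± 1.38 to 126 ± 36.1 CPM (5.38 ± 0.42 SE, adjusted p 0.000194) and CALB1, the calcium-binding protein calbindin, from 0.29 ± 0.02 to 11.2 ± 1.5 (5.25 ± 0.44, adjusted p 0.000223). MFAP5, a microfibril protein gene (ENSG00000197614, chromosome 12, 8637346 to 8662888), rose from 0.04 ± 0.07 to 5.16 ± 1.69 CPM, a ratio of 132 (36.3 to 1100). PTGIS, which encodes prostacyclin synthase, rose from 0.39 ± 0.19 to 13.4 ± 1.8, FGB from 2.35 ± 2.15 to 51.0 ± 20.1, HAPLN1, a hyaluronan link protein gene, from 7.02 ± 3.29 to 89.1 ± 46.3, CLMP from 0.44 ± 0.20 to 5.06 ± 1.22 and ZNF114 from 0.69 ± 0.21 to 6.77 ± 1.22.

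Of the 38 genes, 26 were lower in resistant than in parental cells, opposite in sign to the knockout contrast, 5 were higher in both contrasts and 7 did not pass in resistant against parental. PDPN went from 20.2 ± 7.3 CPM in parental to no reads in resistant and 2.76 ± 1.57 in resistant knockout cells (at least 46.7-fold higher), SH2D4A to 1.03 ± 0.54 (at least 17.4-fold) and MARVELD1 to 0.59 ± 0.30 (at least 10.0-fold), which left each below its parental level. In resistant knockout cells CALB1 stood at 4.7% and MFAP5 at 5.7% of the level in parental knockout cells, and the median of 29 genes that were near 0 in resistant cells stood at 2.67%. Parental RNA in the resistant knockout libraries was not excluded for these 29 genes (5th percentile over median 0.14, bootstrap interval 0.067 to 0.300). In the 5 of them that varied up to 3-fold over the parental libraries, that ratio was 0.653. Independent lists would share 4.9 genes in opposite directions. The covariance of fold changes was -0.441, against a mean of -0.165 in 20 simulations of unchanged knockouts with the same resistant controls. Since both contrasts use the resistant libraries without the knockout, part of the covariance may come from them. In the same simulations opposing genes numbered 0.05 on average and 1 at most, against 26 here. With no knockout effect the simulations called only 0.15 genes on average in the knockout contrast, so few could oppose resistance. For libraries drawn independently, shared controls alone thus rarely gave a call. The simulations cannot show how many of 38 called genes would oppose resistance through shared controls. Leaving out resistant libraries 1, 2 and 3 gave 7, 5 and 4 genes, and leaving out resistant knockout libraries 1, 2 and 3 gave 8, 9 and 17. The overlap then fell to 5, 3, 2, 6, 7 and 11, and to 17 without parental library 1; with a filter of 1 count only it was 233.

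**Figure D3:**
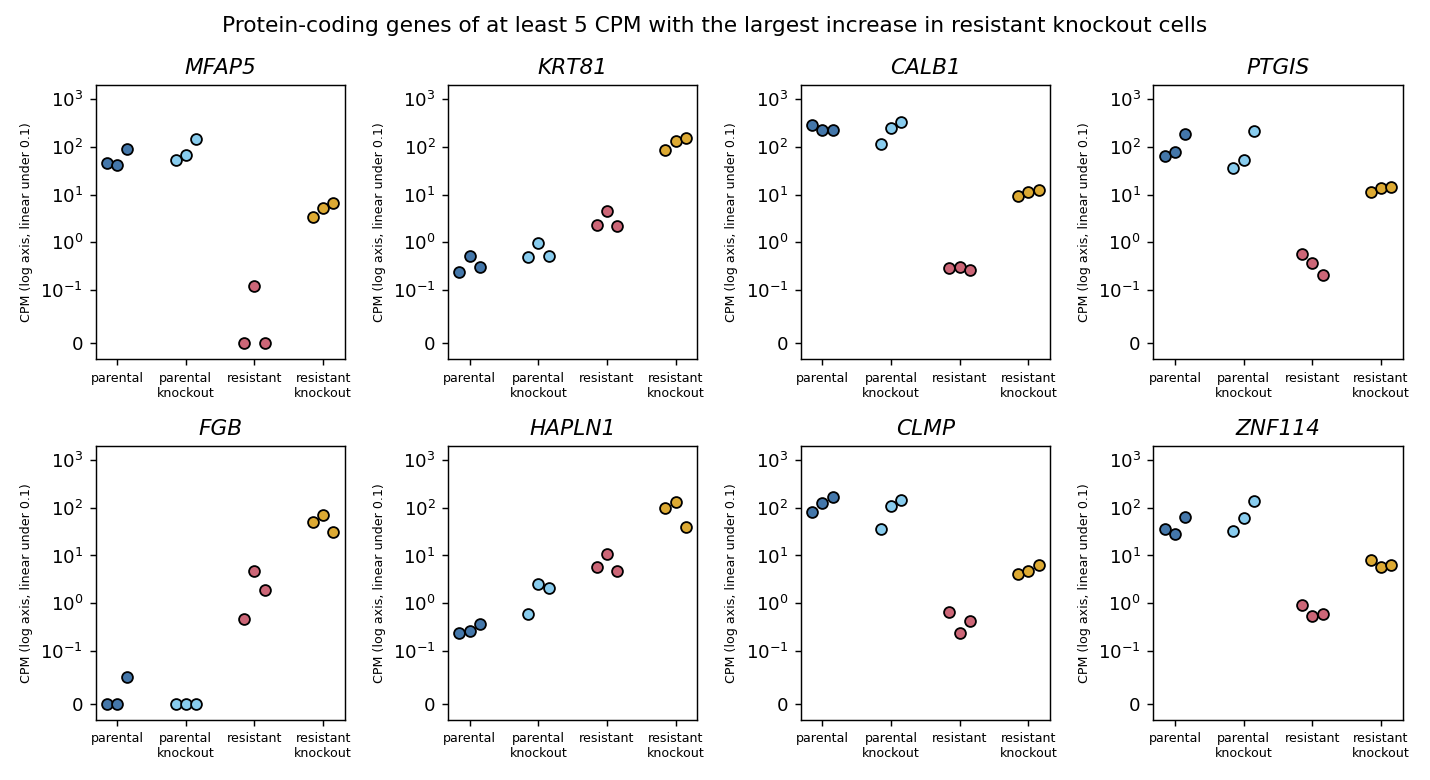
CPM (log axis, linear under 0.1) of the 8 protein-coding genes with the largest increases among those of at least 5 CPM in resistant knockout cells, for each of the 3 libraries in the 4 groups (points). Each gene is higher in the 3 resistant knockout libraries than in the 3 resistant libraries without the knockout, and CALB1, MFAP5, PTGIS, CLMP and ZNF114 remain below both parental groups.

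Cholesterol biosynthesis genes had a median log2 fold change of -1.10 in resistant knockout cells, with 23 of 25 below 0 and 0 past the test for single genes. The unfolded protein and stress response list had a median of -0.74 with 0 of 28 past the test and 9 lower adjusted over the list alone. Camera at the preset correlation called these 2 and interferon-stimulated genes (-0.30) as lower. It called ribosomal protein (0.38), NRF2 and glutathione (0.31), epithelial (0.51, with the tight junction gene CLDN7 higher), NF-kB and cytokine (0.65), oxidative phosphorylation (0.16) and ovarian lineage genes (0.26) as higher. With an estimated correlation 0 of these 9 were called (lowest adjusted p = 0.71), and other splits called up to 13. Without resistant knockout library 3 the count was 5. Ribosomal protein genes made up 4.33%, 3.69% and 5.47% of counts in the resistant knockout libraries, against 2.20% in resistant library 1 and 4.43% and 3.58% in the other two.

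The knockout contrasts of the backgrounds differed for 5 genes by edgeR's test of the difference, all higher in resistant cells: LINC02582 (5.41 ± 0.60 SE on the log2 scale), CALB1 (5.31 ± 0.55), LINC00922 (5.20 ± 0.60), KRT81 (4.49 ± 0.65) and SH2D4A (at least 4.65, with no reads in resistant cells without the knockout). LINC02582 and LINC00922, which encode no protein, were named because the count was small, after their values were seen. SH2D4A, CALB1 and LINC02582 are among the 29 genes for which parental RNA was not excluded, at 3.6%, 4.7% and 5.25% of the level in parental knockout cells. No gene could pass in both knockout contrasts, since 0 passed in parental cells, so this overlap cannot show whether the knockouts act alike. It held 3 genes by DESeq2, 18 with a filter of 1 count only and 27 with the block within backgrounds. Fold changes of the knockout contrasts correlated across genes at r = 0.13 (rho 0.17), and at 0.08 to 0.15 when each library was left out. The count of 5 was 3 without parental library 2 or 3, parental knockout library 1, resistant library 1 or 3, or resistant knockout library 2 or 3, and 8 without parental library 1 or parental knockout library 3. It was 161 with a filter of 1 count only. Of 100 splits of the libraries 9 gave at least 5 genes. With the replicate number as a block the count was 18 in the planned form and 274 (210 higher, 64 lower) within backgrounds, a form chosen after the data were seen. All parental numbers pair, but pairing by number is unclear in resistant cells.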

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

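The test of genes near 0 in parental cells, its check of expected counts, the interval of the share ratio, the size of the TMM factors and the grouping of splits by pairs were chosen after the results were seen; the other tests here were fixed before their results.

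The test of the difference between the knockout contrasts of resistant and parental cells called CALB1 (5.31 on the log2 scale), LINC02582 (5.41), LINC00922 (5.20), KRT81 (4.49) and SH2D4A (at least 4.65, since resistant cells without the knockout had no reads). Of 100 splits of the 12 libraries 9 gave as many genes, with 39 as the highest other count, so chance is not excluded, and a split that calls several times the real count points to structure among the libraries. All 3 parental numbers pair, but pairing by number is unclear in resistant cells. Of the 40 splits that part all 3 parental pairs, as the real one does, 2 gave as many genes (highest other 7), and of the 60 that part 1 pair 7 did (highest 39). The splits were fitted without the block; with it the real count was 18, and 274 (210 higher, 64 lower) within backgrounds, a form chosen after the data were seen. The medians of 7 lists differed by camera at the preset correlation: NRF2 and glutathione (0.28), epithelial (0.41), mitosis (0.42), cholesterol (-1.06), unfolded protein and stress response (-0.41), ribosomal protein (0.34) and ovarian lineage genes (0.31). With an estimated correlation 0 were called (lowest adjusted p = 0.92), and 3 were called at the preset correlation without parental library 3, parental knockout library 1 or resistant knockout library 3. Of the 100 splits 66 called as many lists, the highest other 15, so chance is not excluded for the lists either.

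Genes that were far below their parental level in resistant cells had higher counts in the resistant knockout libraries. Parental RNA in those libraries would give a like share of the parental level in such genes where that level is steady. Over 29 genes the median share was 2.67% (0.12% without the knockout), and the 5th percentile was 0.14 of the median. Low-share genes such as PTX3 (320-fold) and CXCL8 (101.2-fold) varied widely over the parental libraries. In the 5 genes that varied up to 3-fold there, the 5th percentile was 0.653 of the median share of 2.67%. No bound was set for those 5 genes. For the 29 genes a value under 0.2 was set to speak against such a mixture, but the bootstrap interval, 0.067 to 0.300, covers 0.2. The mixture therefore cannot be told apart from a knockout effect for these 29 genes as a set. That test reads low shares only. The highest shares, 13.7% for PDPN and 13.0% for PTGIS, lie above what a mixture at the median share would give. PTGIS varied 6.2-fold over the parental libraries. All 29 were higher, and SH2D4A, CALB1 and LINC02582, 3 of the 5 genes called between backgrounds, are among them. Opposing genes outside the 29 stood at unlike shares of the parental knockout level, such as 3.1% for NEURL1, 6.1% for BCAT1, 51.5% for SLFN11 and 92.3% for STEAP1. A mixture at the median share cannot give the higher of these. For 13 of the 38 called genes the resistant knockout mean exceeded both parental means. A mixture cannot give this for genes such as KRT81 and HAPLN1, but for LINC02323 the excess was slight (0.89 against 0.82 CPM in parental cells). The TMM factors of the resistant libraries span 0.22 on the log2 scale and the smallest change among the 26 opposing genes is 1.83, so the factors cannot give these changes. All 26 kept call and sign under both other scalings, which with such factors could hardly come out otherwise. A knockout effect stays open as a hypothesis. Knockout cells form a single group in each background, so a difference between lines or clones unrelated to the knockout cannot be told apart from it.

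Parental libraries with the same number deviated from their group means together. The lowest correlation stayed at 0.65 after thinning to a common total, which argues against depth. Resistant RNA in the parental libraries numbered 3 stays open only at a small share. Over 37 genes the median share was 0.24%, which leaves little room for shifts in most genes. The 5th percentile over the median was 0, but 17 of the genes would have 3 counts or fewer at that share, so counting alone can give the 0. After removal of the part that follows the mitochondrial share the lowest was 0.18, above the bound of 0.1 but far below 0.78 for that pair, so a part that moves with the mitochondrial share stays open in these 6 libraries. A shared culture day is untested, since the labels give none.

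Resistant and parental cells differed in 5030 genes. In shifted 10 Mb windows with the window's sign lay 30.4% of the called genes, between the bounds set for and against regional gains and losses, which cannot be told apart from other causes here. The share over all tested genes was not computed, and a window's sign comes from the same genes. The window test also called 38 of 267 windows for the parental knockout, where 0 genes passed, against 80 for resistance. The share of higher calls differed by 6.7 percentage points between the shortest and longest genes by exon length (57.0% and 50.3%), which argues against length. Selection under cisplatin, which the design names, stays open and untested.

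With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5030 genes for resistance, 38 for the knockout in resistant cells, 4281 among knockouts and 26 opposing genes. Each was the highest in 1 of 10 splits, with 0 as the highest other. The 26 opposing genes are among the 38, so their 0 in the other splits follows from the 0 called there. For the knockout in parental cells all 10 splits gave 0. For genes shared by both knockouts 0 was fixed in advance, since the parental calls were held at 0 in every split. Lists called were 4 in resistance (10 of 10 splits as many, highest other 13), 5 in the parental knockout (6, highest other 10), 9 in the resistant knockout (7, highest other 13) and 2 among knockouts (10, highest other 11). On the parental libraries alone with the block, 1 of 4 label flips within the pairs, the real one, gave 1206 genes and the highest other 0, again too few flips for a share under 0.05.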

How the results depend on the processing

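Alternatives chosen after seeing the data were the 3 further forms of the replicate block, leaving out both parental libraries numbered 3, and 100000 draws for windows (80 windows, the same as with 10000). No result reversed. The cause of a change was not tested except where stated. The 223 named gene results gave 4902 comparisons with an alternative, of which 4376 stayed, 518 lost their call and 8 gained one. Of 208 called results, 121 passed under every alternative run. With a filter of 1 count only, the knockout changed 83 genes in parental and 451 in resistant cells, 161 differed between backgrounds, 18 were shared and 233 opposed resistance; the correlation was 0.05, and 8 lists were called in parental and 5 among knockouts. Of the 83, 451 and 161 genes, 78, 416 and 160 are genes the filter keeps. DESeq2 gave 11, 249, 67, 3 and 129, and limma-voom 1 in parental cells, 1 shared and 15 opposing. Library size alone gave 11 genes that differed between backgrounds. With only the libraries compared, 11 genes opposed resistance, the correlation was 0.18 and 4 lists were called among knockouts. Without both parental libraries numbered 3, 10 genes differed and 4 lists were called among knockouts.

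Same-numbered resistant libraries correlated at 0.57, -0.19 and 0.64. Resistant libraries 1 and 3 correlated most with the knockout library of the same number, but library 2 did not. Pairing by number is therefore unclear in resistant cells. The planned replicate block gave 1 gene in parental cells and 18 between backgrounds. The block within backgrounds gave 154, 939 in resistant cells (608 higher, 331 lower), 274 between backgrounds and 27 shared, and on the parental libraries alone 1206. The common dispersion was 0.153, 0.121 with the planned block and 0.042 within backgrounds. The block changed no other count by over 1.5 times; with it KDM5A passed in resistant cells.

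An estimated correlation called 0 lists in each of the 5 contrasts; fry called 6 for resistance, 4 among knockouts and 0 in both knockouts and between backgrounds. Leaving out each library gave 3081 to 5411 genes for resistance, 4 to 50 for the resistant knockout, 2714 to 4696 among knockouts, 3 to 8 between backgrounds, 2 to 33 opposing and 0 to 0 in parental cells. List counts ran from 2 to 8 in parental cells, 5 to 13 in resistant cells, 2 to 4 among knockouts and 3 to 10 between backgrounds, and the correlation from 0.08 to 0.15. In simulated counts with the real depth and spread few genes changed 2-fold were recovered; depth and spread were not separated.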

Other observations

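The genes here were chosen after their values were seen, and no test was run on them.

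ERBB2, the receptor tyrosine kinase gene on chromosome 17 (39687914 to 39730426), varied among libraries of the same group. In each numbered parental pair it was lower in the knockout library. It measured 1842, 2633 and 10141 CPM in parental libraries 1, 2 and 3, and 1392, 798 and 4731 CPM in the parental knockout libraries. MIEN1, whose coordinates overlap the end of ERBB2 and which may share reads with it, measured 607, 627 and 2204 CPM and 386, 245 and 962 CPM. PPP1R1B measured 232, 453 and 1051 CPM and 94.2, 153 and 564 CPM. Both were also lower in the knockout library of each numbered pair. PGAP3, whose coordinates also overlap ERBB2, differed from this pattern, with 291, 159 and 314 CPM and 279, 144 and 349 CPM. STARD3, which does not overlap ERBB2, measured 645, 405 and 1097 CPM and 705, 334 and 1404 CPM. GRB7, on the other side, measured 8.1, 6.2 and 21.8 CPM and 5.6, 4.1 and 14.4 CPM. PSMD3, farther along the chromosome, measured 623, 660 and 568 CPM in the parental libraries. In resistant libraries ERBB2 measured 1538, 690 and 718 CPM, and in resistant knockout libraries 811, 1016 and 949 CPM. MIEN1 measured 107, 105 and 76.7 CPM and then 152, 118 and 172 CPM with the knockout. PPP1R1B measured 1.1, 0.7 and 0.1 CPM and then 10.6, 8.7 and 15.7 CPM. The lower levels in the parental knockout pairs were therefore not repeated for these genes in resistant cells, except for ERBB2 in library 1.

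Of 13 leukocyte markers 1 reached 1 CPM in each group (CD68, highest at 54.2 CPM), and of 7 hepatocyte and intestinal markers 1 did, SERPINA1, at 18.8 CPM in parental and 225 CPM in resistant cells. Of 9 fibroblast markers 1 reached 1 CPM in parental, 3 in parental knockout, 5 in resistant and 6 in resistant knockout cells, with COL1A1 highest at 671 and 3651 CPM in the resistant groups. Of 9 endothelial markers 0 reached 1 CPM in parental and 2 in resistant cells (TIE1 highest at 5.2 CPM). Melanocyte and neural markers peaked at SYP with 6.0 CPM in parental and 29.9 CPM in resistant cells, and 4 of 7 mesothelial markers reached 1 CPM in each of those groups.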
